A study of Mus musculus with 6 samples.

How the data were processed

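Bulk RNA sequencing was done on 6 libraries of mRNA-enriched total RNA from mouse B16F10 melanoma cells, 3 control and 3 treated with fenofibrate at 50 µM, which the labels call biological triplicates. Groups were taken from the sample titles. The cell line field runs from B16F10 to B16F15 over the 6 samples in order, so it names a different line for each library. Samples were grouped by title only, and the data cannot settle whether that field is meant as written. If it is, no line occurs in both groups, and line could not be told apart from treatment.

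The deposited table holds, for each library, raw counts per gene and FPKM values made by the authors. The authors' notes name HISAT2 2.0.4, StringTie 1.3.0 and the build GRCm39 without giving their roles. The counting tool, strand setting, trimming and filters are not stated, so the counts of a gene that overlaps another annotated gene can hold reads of that gene. Gene coordinates in the deposited table are those of GRCm38: 99.8% of its gene IDs are in GENCODE M21, and 98.7% of these have the same start and end there. Coordinates are therefore given as GRCm38, which differs from the build named in the notes. The table has 54838 genes, of which 23561 had a count in at least 1 library. The deposited FPKM equals the count divided by one length per gene and by the library's summed counts, within 0.1% between libraries. That length equals the sum of the gene's distinct exons for 97.4% of genes and the merged exon length for 39.6% (tolerance 0.1%). Its median ratio to the merged length was 1.13, with a 90th percentile of 1.85, so FPKM values understate genes with many overlapping exons.

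Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The plan written before the data were examined was a limma test on log2(FPKM + 0.5), to be replaced by edgeR if the file also held raw counts, which it did. Genes were kept with filterByExpr (13629), libraries scaled by TMM, and groups compared with glmQLFit and glmQLFTest with no covariate. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The SE of a log2 fold change is its size divided by the square root of F, and 95% intervals come from the same test. Levels are CPM, counts relative to the library total, and normalised CPM use TMM-scaled totals. The depth of 13540038 to 14710856 counts per library puts the limit for a count of 0 (3 counts) at 0.204 to 0.222 CPM. Reads without molecular identifiers are not independent molecules, so such limits and all counting intervals cover counting error only. Where one group had 0 counts, the fold is a lower bound against 3 counts over the whole group.

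Before the data were examined, 36 pathway lists and 6 lists of markers of other cell types were fixed, with 957 symbols. Of these, 915 matched the table by symbol, 27 through another name and 4 had no match, and the rest were further names of genes already matched. The 35 pathway lists with 4 or more members tested were put to camera on log2 CPM (prior count 0.5, preset correlation 0.01), adjusted over the 35 lists. Camera with an estimated correlation and fry were run beside it. Calls within a list were counted over all genes and adjusted over the list alone. Marker lists were read as summed levels and gene calls. After the data were examined, 6 further lists were written for the closing section: other B-lineage and plasma cell genes, other blood cell genes, other cartilage genes, embryonic connective tissue genes, SMAD target genes and AHR target genes.

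Genes were named by a rule fixed before the data were examined. First came the 10 largest rises and 10 largest falls among called genes with separated groups, a mean of 5 FPKM or more in the higher group and a non-provisional symbol. Second came Ptpn14, Mark1 to Mark4, Yap1, Wwtr1, Lats1, Lats2, Ccn1, Ccn2 and Ppara. Last came, from each list, up to 4 called genes with the largest changes in the direction of most calls and up to 2 in the other. The text leaves out some genes that the rule gives. Genes outside the rule are said to have been chosen after their values were seen. The table gives Ccn1 as Cyr61 and Ccn2 as Ctgf.

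The edgeR test was tested on simulated data with 13629 genes, 13481 of them tested, of which 200 were changed. It called 0% of 50 genes changed 1.25-fold, 58% at 1.5-fold, 70% at 2-fold and 96% at 4-fold, with 10 false calls among 122. The simulation changed 200 genes, while 5326 were called in the data, so these rates need not hold for the real test. A simulated list of 30 genes raised 1.3-fold was called with an adjusted p of 2.79e-27 (preset correlation) and 0.0424 (estimated correlation), and 0 of 200 random lists were called with either. The genes were simulated independently of each other, so these lists cannot show false calls that come from correlation between genes.

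Alternatives were DESeq2 1.42.0 with its size factors, edgeR without a filter on low counts, a block on the replicate number, and leaving out each library in turn. On FPKM, limma was run with pseudocounts of 0.1, 0.5 and 1, with no filter and with minimum means of 1 and 5 FPKM. It was also run after rescaling to TPM, to the median of ratios or to quantiles, without a trend, and with robust moderation. Added after the data were examined were limma on log2(FPKM + 0.5) itself, edgeR with library totals in place of TMM, and edgeR without mitochondrially encoded genes. The replicate numbers do not pair the libraries: the deviations of same-numbered libraries from their group means had correlations across genes of 0.02, 0.01 and -0.02. All 6 libraries and every column of values per sample were used.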

Results

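The RNA of mouse melanoma cells, taken here as the line B16F10, was sequenced after treatment with fenofibrate at 50 µM (n = 3 libraries) and in control cultures (n = 3). Fenofibrate is a lipid-lowering fibrate whose active form is an agonist of the nuclear receptor PPARα. The control libraries held 13594939, 14072673 and 13597959 counts, and the fenofibrate libraries 13540038, 14368623 and 14710856 counts. A count of 0 in one library therefore allows a level of up to 0.204 to 0.222 CPM, the count relative to the library total, and this limit covers counting error only. Mitochondrially encoded genes took 6.23% ± 0.395 of the counts in control and 6.52% ± 0.0850 in fenofibrate (mean ± SD, n = 3 each). The 10 most counted genes of each library took 7.24% ± 0.262 in control and 8.03% ± 0.0441 in fenofibrate. Across genes, which are not independent replicates, the correlation of log2 values was 0.984 to 0.985 between control libraries, 0.986 between fenofibrate libraries and 0.957 to 0.963 between the groups. The first principal component held 60.2% of the variance and separated the groups, and the second held 11%.

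One comparison follows from the design: which transcripts differ between fenofibrate-treated and control melanoma cells, with PTPN14, the MARK kinases and the Hippo pathway named in the series title. Fenofibrate-treated cells held far more RNA of Id3, Id1, Smad6 and Smad9 and of the YAP target genes Ctgf (Ccn2) and Cyr61 (Ccn1). The list of YAP and TAZ targets was not called, with 8 of 22 genes higher and 6 lower, and Yap1 fell while Wwtr1 rose. With a preset correlation, the lists of immediate early, lysosomal, glycolytic and pigmentation genes were called higher, and those of DNA replication, cholesterol synthesis and interferon-stimulated genes lower. These calls were lost at adjusted p values from 0.189 to 0.526 with an estimated correlation. Ptpn14 itself showed no change that passed the test, and Mark4 was the only MARK gene called. Of 13629 genes tested, 5326 (39.1%) passed an adjusted p of 0.05, 2664 higher and 2662 lower with fenofibrate. The median size of these changes was 1.37-fold, and 758 genes changed at least 2-fold, 438 upward and 320 downward. All 3 fenofibrate values lay on one side of the 3 control values for 7258 genes, 53.3% of those tested, where chance gives 10%.

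Of the 10 largest rises among well expressed genes, 9 are described here. Id3, an inhibitor of basic helix-loop-helix transcription factors, went from 4.45 ± 0.353 to 208 ± 9.91 normalised CPM (mean ± SD, n = 3 each), which is 46.8-fold (log2 fold change 5.55 ± 0.08 SE, adjusted p = 3.66e-08). Its gene, ENSMUSG00000007872, lies on chromosome 4 from 136143497 to 136145755. Its relative Id1 rose 28.3-fold. Smad6, an inhibitory SMAD, rose 37.5-fold, and Smad9, a SMAD activated by bone morphogenetic protein receptors, rose 12.3-fold. The other genes in this group were Ctgf (22-fold), the corepressor gene Hr (15.4-fold), the small Maf factor gene Maff (13.6-fold), Vasn (13.1-fold), whose product binds TGF-beta, and Gadd45g (10.4-fold), a growth arrest gene. The 9 genes had adjusted p values from 3.66e-08 to 3.83e-05.

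The largest fall among well expressed genes was that of Gsdmc, a gasdermin gene, from 159.6 ± 1.77 to 20.9 ± 1.90 normalised CPM (mean ± SD, n = 3 each), which is 7.64-fold lower (log2 fold change -2.93 ± 0.07 SE, adjusted p = 6.85e-07). Txnip, whose product restrains glucose uptake and thioredoxin, was 4.94-fold lower. Csf1, the macrophage colony-stimulating factor, was 3.72-fold lower. The others were Tfap4 (3.95-fold lower), the lysophosphatidic acid receptor gene Lpar5 (3.77-fold), Inka1 (3.67-fold), the deoxycytidylate deaminase gene Dctd (3.41-fold), Zbtb12 (3.19-fold) and Prdm16 (2.73-fold). Of the 10 largest falls these 9 are described, and their adjusted p values ran from 6.85e-07 to 0.00181. Ctgf, Vasn, Txnip, Zbtb12 and Prdm16 overlap another annotated gene, and with no strand stated for the libraries their counts can hold reads of the overlapping gene.

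**Figure D1:**
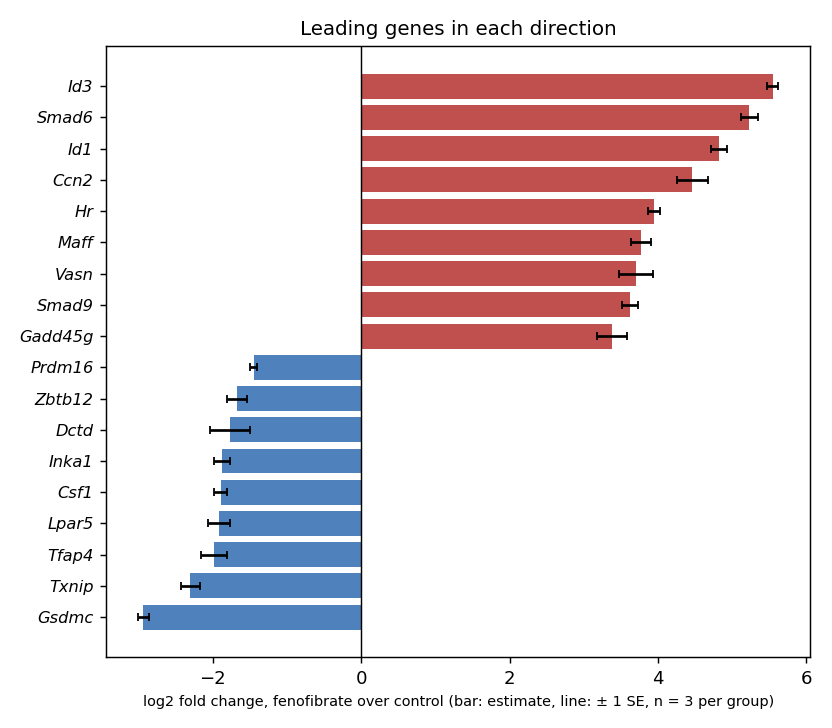
Log2 fold change of fenofibrate over control for 9 of the 10 largest rises and 9 of the 10 largest falls among well expressed genes, as the model's estimate (bar) with 1 SE on each side (line), n = 3 libraries per group. The rises run from 3.38 to 5.55 and the falls from -1.45 to -2.93.

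Ptpn14, a protein tyrosine phosphatase that binds YAP, was counted 3546, 3774 and 3260 times in the control libraries and 3193, 3127 and 3799 times with fenofibrate. Its level was 252 ± 13.8 against 242 ± 21.2 normalised CPM (mean ± SD, n = 3 each). The log2 fold change was -0.06 ± 0.07 SE, with a 95% interval from -0.22 to 0.11 (adjusted p = 0.561), so that a fall below 0.859 of control or a rise above 1.08-fold lies outside the interval. Without fenofibrate replicate 2 the log2 fold change was 0.00. The gene, ENSMUSG00000026604, lies on chromosome 1 from 189728268 to 189876695 and overlaps another annotated gene.

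The MARK genes encode kinases that phosphorylate microtubule-associated proteins. Mark4 (ENSMUSG00000030397, chromosome 7, 19424775 to 19458821) fell from 45.4 ± 3.23 to 26.7 ± 7.61 normalised CPM (mean ± SD, n = 3 each). Its log2 fold change was -0.76 ± 0.18 SE, with a 95% interval from -1.18 to -0.34 (adjusted p = 0.0126), and it was lower in 3 of 3 fenofibrate libraries than in every control. Mark2 had a log2 fold change of 0.11 ± 0.08 (adjusted p = 0.272) and Mark3 of 0.08 ± 0.06 (adjusted p = 0.317). Without fenofibrate replicate 3, Mark3 passed the threshold (log2 fold change 0.14, adjusted p = 0.0383). Mark1 was counted 0 times in all 6 libraries. Of the 3 MARK genes tested, 0 rose and 1 fell, also when adjusted over the list alone, and the median (0.08) and the mean (-0.19) of their log2 fold changes differ in sign. A list of 3 genes was not put to the list test.

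Of 28 Hippo core kinases and regulators tested, 8 rose, 9 fell and 11 were not called, with the same 8 and 9 when adjusted over the list alone. The list as a whole was not called (median log2 fold change -0.01, mean 0.06, adjusted p = 0.780). The DNA-binding partners of YAP went both ways: Tead4 rose 3.29-fold, while Tead3 was 1.79-fold and Tead2 1.43-fold lower. Wwc1, which activates the LATS kinases, was 1.53-fold lower. Yap1, the pathway's effector, fell by 0.32 ± 0.04 on the log2 scale (adjusted p = 0.000768), and its paralog Wwtr1 (TAZ) rose by 0.56 ± 0.05 (adjusted p = 0.0002). Lats1, a kinase that phosphorylates both, rose 1.2-fold (adjusted p = 0.00212). Lats2 had a log2 fold change of 0.56 ± 0.25 (95% interval -0.02 to 1.13, adjusted p = 0.113). Yap1 and Lats2 overlap another annotated gene. The members Mob1a and Tead1, chosen after their values were seen, were counted unevenly within the control group. Mob1a had 900, 966 and 4337 counts there and 4968, 5092 and 5450 with fenofibrate (adjusted p = 0.105), and Tead1 had 377, 199 and 898 against 225, 202 and 185 (adjusted p = 0.0792).

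The targets of YAP and TAZ also split. Cyr61, a matricellular protein gene, rose 6.31-fold, from 108 ± 5.12 to 684 ± 55.5 normalised CPM (mean ± SD, n = 3 each, adjusted p = 8.35e-07), and Ctgf from 15.1 ± 3.64 to 334 ± 68.3 (adjusted p = 1.32e-05). The stress gene Gadd45b rose 3.43-fold and the tissue factor gene F3 1.81-fold, while Tgfb2 was 1.54-fold and Wwc1 1.53-fold lower. Of 22 targets tested, 8 rose, 6 fell and 8 were not called, with the same numbers when adjusted over the list alone. The list was not called (adjusted p = 0.460). Its median was -0.03, while its mean of 0.40 and its test pointed upward.

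**Figure D2:**
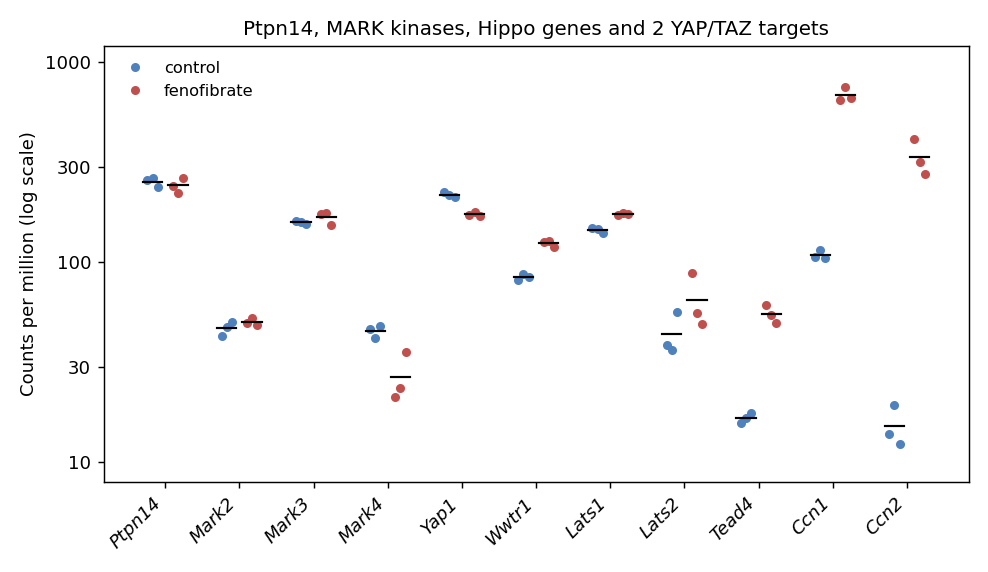
Normalised CPM (log scale) of each control (blue) and fenofibrate (red) library for Ptpn14, MARK, Hippo and YAP target genes, with the mean of 3 libraries as a line. Ptpn14 lay near 252 and 242 in the groups, while Ccn2 went from 15.1 to 334.

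Genes of lipid metabolism moved in opposite directions. Of 26 PPAR target genes tested, 12 rose, 2 fell and 12 were not called, with the same numbers when adjusted over the list alone. The median log2 fold change was 0.30 (adjusted p = 0.00287, and adjusted p = 0.207 with an estimated correlation). Acadvl, a mitochondrial acyl-CoA dehydrogenase gene, rose 1.44-fold, and Klf10, a transcription factor, 1.44-fold. Fabp5 (1.18-fold lower) and Ehhadh (1.36-fold lower) fell. Several textbook PPARα targets, chosen here after their values were seen, were hardly counted. Pdk4 and Cyp4a14 had 0 counts in all 6 libraries, and Angptl4 had 13 in control and 10 with fenofibrate. Ppara (ENSMUSG00000022383, chromosome 15) had 36 counts over the controls and 23 over the fenofibrate libraries, too few to be tested. Of 21 genes of mitochondrial fatty acid oxidation, 10 rose, 0 fell and 11 were not called, with the same numbers over the list alone (median 0.19, adjusted p = 0.000263). That call was lost at adjusted p = 0.189 with an estimated correlation. Its members Etfdh (1.41-fold), Cpt1a (1.43-fold), the carnitine palmitoyltransferase of the outer mitochondrial membrane, and Slc25a20 (1.32-fold) rose.

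Of 24 genes of cholesterol biosynthesis and uptake, 14 fell, 2 rose and 8 were not called, with 15 lower and 2 higher when adjusted over the list alone. The median log2 fold change was -0.45 (adjusted p = 9.73e-06, and adjusted p = 0.189 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, was 2.41-fold lower, and Fdft1, the squalene synthase gene, 1.77-fold. Tm7sf2, a sterol reductase gene, rose 3.22-fold. Of 20 genes of fatty acid synthesis and desaturation, 10 fell, 4 rose and 6 were not called, with the same numbers over the list alone. The elongase gene Elovl6 was 1.92-fold lower, the desaturase gene Scd1 1.71-fold and Fads2 1.57-fold, while Dgat1, which makes triglycerides, rose 1.71-fold. This list missed the threshold (median -0.25, adjusted p = 0.0523). It passed in 14 of 23 alternative settings. On counts, these were the fits without control replicate 1 (adjusted p = 0.0488), without control replicate 3 (0.0343), without fenofibrate replicate 3 (0.0466) and without a filter (0.00767). On FPKM it passed in 9 of 10 limma fits (0.00737 to 0.0398), among them the test first planned (0.0374), and it passed with fry.

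In 4 lists of proliferation and biosynthesis, called genes that fell outnumbered those that rose. Of 40 DNA replication and G1/S genes, 31 fell, 1 rose and 8 were not called, with 34 lower and 1 higher when adjusted over the list alone (median -0.41). The adjusted p was 3.14e-11, and adjusted p = 0.189 with an estimated correlation. The cyclin gene Ccnd1 was 2.04-fold lower (209 ± 1.29 to 102 ± 9.38 normalised CPM, mean ± SD, n = 3 each). Uhrf1, which maintains DNA methylation, was 1.73-fold lower, the thymidylate synthase gene Tyms 1.64-fold and the polymerase subunit gene Pola2 1.55-fold. Of 40 G2/M and mitosis genes, 15 fell, 1 rose and 24 were not called, with 16 lower and 2 higher over the list alone. Their median was -0.13 (adjusted p = 0.000617, and adjusted p = 0.265 with an estimated correlation). The mitotic kinase genes Ttk and Plk1 were 1.56-fold and 1.47-fold lower, and Ccnb2 rose 1.18-fold. Of 30 ribosome biogenesis and MYC target genes, 16 fell, 3 rose and 11 were not called, also over the list alone. Their median was -0.19 (adjusted p = 0.000582, and adjusted p = 0.265 with an estimated correlation). The spermidine synthase gene Srm was 1.70-fold lower, and the pseudouridine synthase gene Dkc1 1.60-fold. Of 22 genes of glutamine, serine and one-carbon metabolism, 11 fell, 3 rose and 8 were not called, also over the list alone. Their median was -0.20 (adjusted p = 0.0075, and adjusted p = 0.207 with an estimated correlation). Psat1 and Shmt2, enzymes of serine and glycine synthesis, were 1.60-fold and 1.48-fold lower.

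In 5 lists of energy production, hypoxia, lysosomes and pigment, called genes that rose outnumbered those that fell. Of 38 lysosome and autophagy genes, 29 rose, 0 fell and 9 were not called, with 31 higher and 1 lower over the list alone. Their median fold was 1.3 (adjusted p = 1.79e-10, and adjusted p = 0.189 with an estimated correlation). The cathepsin gene Ctsb rose 1.83-fold and Psap, which encodes activators of lysosomal lipid breakdown, 1.76-fold. Of 20 glycolysis genes, 17 rose, 1 fell and 2 were not called, with 18 higher and 1 lower over the list alone. The list had a median fold of 1.38 (adjusted p = 6.52e-08, and adjusted p = 0.189 with an estimated correlation). The lactate transporter gene Slc16a3 rose 2.11-fold and the glucose transporter gene Slc2a1 1.74-fold, while the hexokinase gene Hk1 was 1.33-fold lower. Of 21 hypoxia-induced genes, 11 rose, 2 fell and 8 were not called, also over the list alone. Their median fold was 1.26 (adjusted p = 0.0049, and adjusted p = 0.207 with an estimated correlation). Ndrg1 rose 3.44-fold, Adm, which encodes adrenomedullin, 3.17-fold and the mitophagy gene Bnip3 2.46-fold. The mTORC1 inhibitor gene Ddit4 was 2.21-fold lower. Of 46 nuclear-encoded oxidative phosphorylation genes, 22 rose, 0 fell and 24 were not called, with 23 higher over the list alone. The list had a median fold of 1.13 (adjusted p = 4.18e-06, and adjusted p = 0.207 with an estimated correlation), with Cox7c at 1.49-fold and Cox6c at 1.37-fold. Of 23 genes of melanocyte differentiation and pigmentation, 17 rose, 1 fell and 5 were not called, with 19 higher and 1 lower over the list alone. Their median fold was 1.26 (adjusted p = 1.11e-07, and adjusted p = 0.207 with an estimated correlation). Mitf, the master transcription factor of melanocytes, rose 2.27-fold and Mlph, a melanosome transport gene, 1.95-fold, while the receptor gene Kit was 3.12-fold lower.

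Immediate early genes, which respond within minutes to growth factors and stress, rose almost throughout. Of 22 tested, 21 rose, 0 fell and 1 was not called, also over the list alone. The median fold was 2.01 (adjusted p = 4.05e-10, and adjusted p = 0.189 with an estimated correlation). The phosphatase gene Dusp1 rose 8.89-fold and the AP-1 genes Fosl2 and Fosb 8.86-fold and 5.94-fold. Of 13 actin cytoskeleton genes driven by SRF, 9 rose, 1 fell and 3 were not called, also over the list alone. The list had a median fold of 1.63 (adjusted p = 0.00014, and adjusted p = 0.243 with an estimated correlation). The focal adhesion genes Zyx and Vcl rose 3.10-fold and 2.40-fold, and Srf itself 2.52-fold. Of 18 genes that report ERK pathway output, 10 rose, 6 fell and 2 were not called, with 10 and 7 over the list alone, and the list was not called (adjusted p = 0.297). The feedback inhibitor gene Spry2 rose 3.18-fold, and Etv1 was 2.10-fold lower. Of 21 mesenchymal and matrix genes, 11 rose, 4 fell and 6 were not called, also over the list alone. Their median fold was 1.31 (adjusted p = 0.0286, and adjusted p = 0.307 with an estimated correlation). Without a filter on low values this call was also lost, at an adjusted p of 0.105 with edgeR on counts and 0.0695 with limma on FPKM. Thbs1, a matrix glycoprotein gene, rose 5.5-fold and the integrin gene Itgb3 2.59-fold. Col1a2, a collagen gene, was 3.13-fold and Zeb2, a repressor of epithelial genes, 1.49-fold lower. Of 5 epithelial adhesion genes, 2 rose, 1 fell and 2 were not called, also over the list alone (adjusted p = 0.482). The plakophilin gene Pkp2 rose 3.05-fold and Tjp1 was 1.38-fold lower. Of 8 neural crest and dedifferentiation genes, 4 rose, 1 fell and 3 were not called, also over the list alone (adjusted p = 0.0957, and under the threshold in 3 of 23 alternative settings, with 0.0372 without fenofibrate replicate 3). S100b rose 2.58-fold and Pdgfrb was 1.8-fold lower.

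Of 28 interferon-stimulated genes, 15 fell, 2 rose and 11 were not called, also over the list alone. Their median log2 fold change was -0.25 (adjusted p = 0.000629, and adjusted p = 0.526 with an estimated correlation). The transcription factor gene Irf1 was 2.43-fold, Ifi44 1.81-fold and the GTPase gene Gbp3 1.67-fold lower, while Gbp2 rose 1.38-fold. Of 13 NF-kB and inflammatory genes, 9 fell, 3 rose and 1 was not called, with 9 and 4 over the list alone. The list missed the threshold (median -0.43, adjusted p = 0.0509) and passed in 10 of 23 alternative settings, on counts without control replicate 2 (0.0419) and without fenofibrate replicate 1 (0.0321), 2 (0.0447) or 3 (0.0456), with DESeq2 (0.0467), without a filter on counts (0.00365) and without mitochondrially encoded genes (0.0487). The chemokine gene Cxcl1 was 6.10-fold lower, and the NF-kB feedback gene Tnfaip3 1.65-fold. The cytokine gene Lif rose 6.59-fold. Of 14 genes for cell-surface ligands and immune checkpoints, 6 fell, 3 rose and 5 were not called, also over the list alone (adjusted p = 0.154). Cd276, which encodes the checkpoint ligand B7-H3, was 1.93-fold lower, Nectin2 1.86-fold and Cd274, which encodes PD-L1, 1.78-fold, while the galectin gene Lgals3 rose 1.88-fold. Of 14 genes of antigen processing and presentation, 3 fell, 2 rose and 9 were not called, also over the list alone (adjusted p = 0.305). The class I gene H2-Q4 was 1.74-fold and the peptidase gene Erap1 1.36-fold lower. Cd74, the invariant chain gene of B-lineage and myeloid cells, had the largest change of the list, a rise from 16 counts over the controls to 135 with fenofibrate (8.30-fold, adjusted p = 0.00181).

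The stress and housekeeping lists were not called. Of 33 ATF4 target genes of the integrated stress response, 12 fell, 6 rose and 15 were not called, with 15 and 9 over the list alone (adjusted p = 0.0697, and under the threshold in 5 of 23 alternative settings, with 0.0480 without control replicate 2 and 0.0338 without a filter on counts). Atf3 rose 5.38-fold and the amino acid transporter gene Slc3a2 2.82-fold, while Sesn2 was 1.76-fold and Phgdh 1.67-fold lower. Of 21 genes of the unfolded protein response, 8 fell, 2 rose and 11 were not called, also over the list alone (adjusted p = 0.162, and under the threshold in 3 of 23 alternative settings, with 0.0291 without fenofibrate replicate 3). Xbp1 was 1.41-fold lower and Dnajb9 rose 1.40-fold. Of 26 NRF2 response genes, 12 rose, 7 fell and 7 were not called, with 13 and 8 over the list alone (adjusted p = 0.155). The heme oxygenase gene Hmox1 rose 2.16-fold and Gclc, of glutathione synthesis, 1.97-fold, while Gsr was 1.59-fold lower. Of 14 metallothionein and heat shock genes, 4 rose, 3 fell and 7 were not called, also over the list alone (adjusted p = 0.780). Their median of -0.10 differed in sign from their mean of 0.07, and Mt1 rose 2.03-fold. Of 17 ferroptosis and iron genes, 7 rose, 2 fell and 8 were not called, also over the list alone (adjusted p = 0.155). The cystine transporter gene Slc7a11 rose 1.59-fold and the iron exporter gene Slc40a1 was 1.70-fold lower. Of 25 p53 target genes, 5 rose, 6 fell and 14 were not called, with 7 and 7 over the list alone (adjusted p = 0.915). Their median of -0.01 and mean of -0.03 were negative, while the test pointed upward. Plk2 rose 2.94-fold and the pro-apoptotic gene Bbc3 was 3.23-fold lower. Of 25 apoptosis regulators, 5 rose, 7 fell and 13 were not called, with 6 and 7 over the list alone (adjusted p = 0.793). Cflar, which restrains caspase activation, rose 2.36-fold, and Bid was 1.62-fold lower. Of 57 cytosolic ribosomal protein genes, 9 rose, 1 fell and 47 were not called, with 1 and 1 over the list alone (median 0.08, adjusted p = 0.0509). That list passed in 7 of 23 alternative settings, on counts with a block on replicate number (0.0440), with DESeq2 (0.0467), without a filter on counts (0.0235), without mitochondrially encoded genes (0.0487), without control replicate 3 (0.0242) or without fenofibrate replicate 3 (0.0187). Of 12 histone genes, 5 rose, 0 fell and 7 were not called, also over the list alone (adjusted p = 0.0523). The histone list passed in 10 of 23 alternative settings, on counts without control replicate 2 (0.0398) or 3 (0.0326) or with library totals (0.0449). Among the others were the test first planned, limma on log2(FPKM + 0.5) (0.0374), and fry. The linker histone gene Hist1h1c rose 8.02-fold. Of 13 mitochondrially encoded genes, 4 rose, 2 fell and 7 were not called, also over the list alone (adjusted p = 0.398). The complex I subunit genes mt-Nd5 and mt-Nd3 went apart, with a 1.34-fold rise and a 1.55-fold fall.

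**Figure D3:**
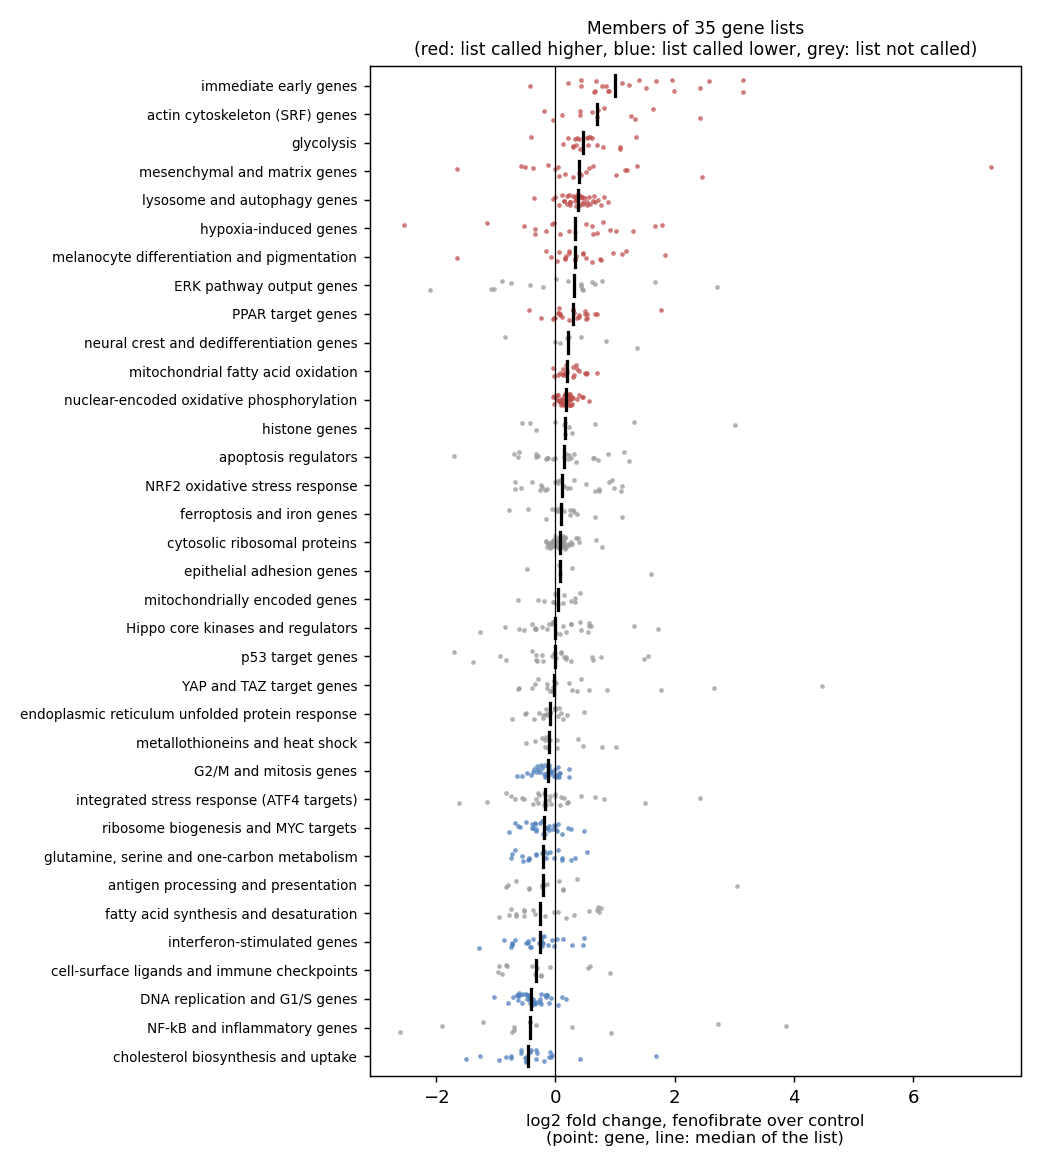
Log2 fold change of fenofibrate over control for each tested member (point) of 35 gene lists, with the median of each list as a line. Lists called higher are red, lists called lower blue and lists not called grey, and the medians run from -0.45 for cholesterol biosynthesis and uptake to 1.01 for immediate early genes.

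Markers of other cell types were scarce in both groups. Summed T cell markers stood at 5.38 ± 0.391 CPM in control and 4.84 ± 0.800 with fenofibrate (mean ± SD, n = 3 each). Macrophage markers stood at 2.68 ± 0.633 and 5.68 ± 1.32, endothelial markers at 25.3 ± 2.80 and 31.1 ± 2.91, keratinocyte markers at 8.22 ± 0.442 and 9.47 ± 0.677, and adipocyte markers at 3.77 ± 0.911 and 2.82 ± 0.635. Fibroblast markers stood at 24.7 ± 1.95 and 9.09 ± 0.725. Of all markers 4 were called: Cd68 (adjusted p = 0.0489), Vwf and Fap rose and Col1a2 fell, named after their values were seen. Leaving out 1 library at a time gave 3 to 4 called markers, not always the same ones. Cd68 missed the threshold without control replicate 1 (adjusted p = 0.135) or 3 (0.136) and without fenofibrate replicate 1 (0.150) or 3 (0.0893). It passed without control replicate 2 (0.0307) or fenofibrate replicate 2 (0.0276). It also missed without a filter on counts (0.0913), with a block on replicate number (0.0961) and with library totals (0.0586). Vwf, Fap and Col1a2 passed in each of these fits. Col1a2 is also counted above among the matrix genes.

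The gene test was edgeR's quasi-likelihood F test on counts scaled by TMM, with a common biological coefficient of variation of 0.113. With library totals in place of TMM, 5460 genes passed, 2180 higher and 3280 lower (39.9% higher against 50.0%), so the balance between rises and falls depends on the scaling. Of 35 lists tested, 16 were called by camera with a preset correlation, 10 higher and 6 lower, and 0 held with an estimated correlation, where 8 had an unadjusted p under 0.05. Other splits of the libraries into 3 and 3, which mix control and fenofibrate, called 5 to 15 lists with the preset correlation. With fry, which tests whether a list's genes move one way on balance and not against other genes, 29 passed.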

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

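Tests added after seeing the data were limma on log2(FPKM + 0.5), edgeR with library totals and edgeR without mitochondrially encoded genes. Leaving out 1 library at a time gave 4248 to 4782 genes changed (2112 to 2412 higher, 2136 to 2370 lower), 715 to 805 changed at least 2-fold, 16 to 19 Hippo and MARK genes, 3 to 4 cell type markers and 17 to 21 lists. In each of these 6 fits 3618 of the 5326 calls were shared, and 611 of the 758 changes of at least 2-fold. DESeq2 called 4446 genes (649 at least 2-fold), edgeR without a filter 4614 and edgeR with a block on replicate number 4540. The count of genes changed at least 2-fold fell from 758 in every limma fit on FPKM: 274 with a pseudocount of 0.5, 371 with 0.1, 203 with 1, 309 without a filter, 133 with a mean of 5 FPKM or more, 356 as TPM, 276 with the median of ratios, 270 after quantile normalization, 269 without trend and 272 with robust moderation. Of the 758, 389 reached a mean of 1 FPKM and so were tested by limma, of which 260 were called at least 2-fold, 127 below 2-fold and 2 not called, so fewer genes tested and smaller folds both lower the count. With a mean of 5 FPKM or more, 3270 genes changed and 1381 rose, because fewer genes were tested (6798 against 11713): on these 6798 genes the fit with a mean of 1 FPKM or more called 3166, 1335 of them higher. As TPM 1747 rose, against 1910 on FPKM as deposited, 2116 after quantile normalization and 2372 with the median of ratios on the same 11713 genes, so the scaling moves this number. The number of cell type markers called fell from 4 to 0 with limma on FPKM at each pseudocount, at 5 FPKM, as TPM, without trend and with robust moderation, to 1 with the median of ratios and to 2 after quantile normalization, and it was 3 without a filter. The filter takes out Col1a2, Vwf and Fap, each under a mean of 1 FPKM and called by limma without a filter. Cd68 is tested at 1 FPKM and lies near the threshold, with an adjusted p of 0.0473 after quantile normalization and 0.0543 to 0.0694 in the other fits on FPKM with that filter. The lowest correlation within a group, 0.984, became 0.978 without a filter on counts, and on FPKM 0.980 with a pseudocount of 0.1, 0.988 with 1 and 0.990 without a filter, since the pseudocount and the genes kept set the weight of low values. The number of lists called went from 16 to 0 with an estimated correlation, so these calls depend on which form of the test is used. The preset value of 0.01 alone does not account for the loss. Mitochondrial fatty acid oxidation had an estimated correlation of -0.029, below the preset, and its call was also lost (adjusted p = 0.189). The other called lists had estimates above the preset, from 0.0217 to 0.614. The simulated list, whose genes were drawn independently, also went from an adjusted p of 2.79e-27 with the preset to 0.0424 with the estimate. The estimated form can thus give larger p values without correlation between genes. With fry, which asks another question of the lists, the number called went to 29.

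Among single genes, the result of Ptpn14 reversed, at 0.0046 without fenofibrate replicate 2, with -0.12 to 0.0046 over the fits without 1 library (adjusted p over all its alternatives 0.174 to 0.964). No called gene among those named and no called list reversed. Among lists not called, the test of p53 target genes turned downward in 11 settings. Its median was -0.022 without fenofibrate replicate 3 (-0.022 to 0.018 over the fits without 1 library). On FPKM it was -0.0706 with a pseudocount of 0.5, at 5 FPKM, without trend and with robust moderation, -0.0718 with 0.1, -0.0692 with 1, -0.031 without a filter, -0.088 as TPM, -0.017 with the median of ratios and -0.0601 after quantile normalization. The test of apoptosis regulators turned downward on FPKM, with medians of -0.0655 with a pseudocount of 0.5, without trend and with robust moderation, -0.0665 with 0.1, -0.0642 with 1, 0.028 without a filter, -0.011 with the median of ratios and -0.0591 after quantile normalization. That of epithelial adhesion genes turned with medians of -0.0049 without a filter on counts, -0.14 without control replicate 3 (-0.19 to 0.27 over the fits without 1 library) and 0.011 without a filter on FPKM. Mitochondrially encoded genes turned after quantile normalization (median 0), and heat shock genes with fry (adjusted p = 0.46). The cause was not tested. Genes below the minimum of a setting had no value there. Over all alternatives, called named genes kept direction and call in 3730 results and missed the threshold in 254. Called lists kept theirs in 350 and missed in 18, 16 of these with the estimated correlation. Among named genes not called 1 result passed, and among lists not called 59.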

Other observations

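Genes in this part were chosen after their values were seen, as were the lists named as further lists, the test on Sox9 and Hapln1 and the share of the cartilage genes without Hapln1; the bounds for the other tests were written before their results. Further SMAD-linked genes rose with fenofibrate, though Bambi, looked at beside them, did not pass (log2 fold change 0.32 ± 0.20 SE, adjusted p = 0.254). Nog, a secreted antagonist of bone morphogenetic proteins, had 0 counts in the controls and 106, 122 and 133 with fenofibrate, at least 121-fold higher (3 counts over the control group). The inhibitory SMAD gene Smad7 had 634 counts over the controls and 5011 over the fenofibrate libraries (log2 fold change 2.99 ± 0.09 SE, adjusted p = 2.34e-06). Id2 rose by 2.91 ± 0.04 on the log2 scale (adjusted p = 3.66e-08), and Atoh8, a helix-loop-helix factor gene, by 2.99 ± 0.14 (adjusted p = 1.21e-05). A hypothesis from these genes is that fenofibrate-treated cells show a wider SMAD response. SMAD target genes outside the leading ones were listed after those were seen, and of 30 tested 14 rose and 3 fell. Their median log2 fold change was 0.31 and their mean 0.47 (camera p = 0.00088 with a preset correlation and p = 0.0282 with an estimated correlation, 1 list). Examples of the rises are Skil, Ski and Pmepa1, which encode inhibitors of SMAD signalling. The list was not divided between targets of bone morphogenetic proteins and of TGF-beta. The shift may reflect SMAD activity, but the data hold no measure of SMAD phosphorylation, and the list came from the same libraries.

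Some genes induced through the aryl hydrocarbon receptor rose. Cyp1a1, a monooxygenase gene, had 1 count over the controls and 65 over the fenofibrate libraries, a ratio of 65.4 (95% counting interval 11.3 to 2621). Of the list of AHR target genes 4 were tested, of which Tiparp (log2 fold change 1.08 ± 0.06, adjusted p = 2.69e-05) and Nqo1 (0.94 ± 0.18, adjusted p = 0.00453) rose and 0 fell. Ahrr, a repressor induced by the receptor, had a log2 fold change of -0.08 ± 0.21 (adjusted p = 0.783). Fgf21, a hormone gene controlled by PPARα and ATF4, had 3 counts over the controls and 22 with fenofibrate, a ratio of 7.38 (95% counting interval 2.22 to 38.5).

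Immunoglobulin genes were counted with fenofibrate and not in control: Igkc had 0 counts in the controls and 25, 38 and 20 with fenofibrate, Ighm 0 and 64 in all, Igha 0 and 49, and Jchain 0 and 40. Transcription of unrearranged constant regions in the melanoma cells would leave variable segments silent, yet 76 of 218 variable segments in the table were counted with fenofibrate (177 counts) and 0 in control, 76 above control, which argues against it. The 76 segments are what reads from B-lineage cells or from another mouse library may leave, and the bound was at least 10 segments. The genes Ptprc (0 and 24 counts), S100a9 (0 and 33) and Hbb-bs (0 and 10), of other blood cells, also had counts with fenofibrate only, and Cd74, of B-lineage and myeloid cells, went from 16 to 135 counts, while 17 further B-lineage and plasma cell genes had 88 counts in control and 153 with fenofibrate, and of 4 further blood cell genes tested 0 rose and 1 (Arhgdib) fell. Whether such reads came from cells or from another library stays open.

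Col2a1, Col9a1, Col11a1, Acan and H19, genes of cartilage or embryonic tissue, were counted almost only in control, most in control replicate 3, while other such genes went both ways. Col2a1 had 171, 171 and 720 counts in control and 14, 14 and 23 with fenofibrate, Col9a1 169 over the controls and 3 with fenofibrate, Col11a1 177 and 3, Acan 100 and 2, H19 152 and 0, and Igf2 4, 3 and 100 in control and 0 with fenofibrate. Control replicate 3 held 66.5% of the control counts of the 5 leading genes (Col2a1, Col9a1, Col11a1, Acan and H19) and 33% of all control counts. A cartilage programme of the melanoma cells lowered by fenofibrate stays open: Sox9, its transcription factor, had a log2 fold change of -0.0056 ± 0.19 (adjusted p = 0.986), while Hapln1, counted 1299 times in control and 617 times with fenofibrate, fell by 1.07 ± 0.08 on the log2 scale (adjusted p = 7.77e-05). Reads from cartilage or embryonic tissue cannot be told apart from it: other cartilage genes had 39.5% of their control counts in replicate 3, under the 45% set beforehand as the bound against such reads, but 52.1% of those counts were of Hapln1, which both groups express and which hides a small share of other reads, so that bound was wrong, a reason found after the result. Without Hapln1 the share was 45.1%, between that bound and the 66.5% of the leading genes, which decides nothing. The 16 other cartilage genes had 2493 counts in control and 1604 with fenofibrate. Of these genes 14 had 10 or more counts, 10 of them lower with fenofibrate, and 7 were tested, of which 2 rose (Col10a1 and Col11a2, the latter from 270 counts to 420) and 2 fell (Hapln1 and Col27a1). Of 4 tested embryonic connective tissue genes 1 rose (Postn) and 1 fell (Col1a2).

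Counts of 57 genes with at least moderate expression jumped 4-fold or more between replicates of a group, and 4 of these genes were called. One example is Kctd12, with 938, 0 and 0 counts in control and 1949, 2129 and 1781 with fenofibrate (adjusted p = 0.151). A single deviating culture is argued against by the spread of the outlying library: the most frequent one stood apart in 21.1% of the genes. This lies under the bound set beforehand of 1 in 3. Expression that differs between cultures from gene to gene would spread in the same way, so the test cannot decide on it. The reads may have been assigned to one of several overlapping annotated genes, since 52.6% of the 57 overlap another gene against a median of 36.8% (central 95% of sets 24.6% to 49.1%) in 10000 sets of genes of matched level (one-sided permutation p = 0.009). Overlap leaves part of the pattern open, because Mob1a and Tead1 overlap no gene.

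With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In 1 of the 10 splits, the real one, 5326 genes were called, against at most 2 in another split, and 758 genes changed at least 2-fold in 1 of 10, against at most 2. Every other split holds control and fenofibrate libraries on each side, so a difference between the groups widens the spread within its sides. Few gene calls there follow from the design, whether treatment or chance made the difference, so these counts cannot speak against chance. For lists, 16 were called in 1 of 10 splits, the real one, against at most 15 in another split, and other splits called 5 to 15 lists. The number of lists called with the preset correlation therefore barely sets the real split apart.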
